A study of Mus musculus with 6 samples.

How the data were processed

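RNA of red pulp macrophages sorted from the spleens of 3 wild-type and 3 Bach2 knockout mice was measured on 6 single-colour Agilent mouse arrays. Per the labels' protocols, the RNA was isolated with a micro-scale column kit, amplified and labelled with a cyanine dye after amplification. The markers of the sort gate are not given in the sources used here. The groups come from the genotype given for each sample, the replicates are separate mice and were numbered 1 to 3 within a genotype in the order of the records, and the labels give the sex and an age of 8 to 9 weeks. The labels carry an animal tag for each mouse, 1 of which is shared by a wild-type and a knockout mouse (replicate 3 of each), and its meaning is not stated.

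The deposited scanner output holds spot intensity values that the authors read with Agilent Feature Extraction. The version is 9.1 per the submitters' processing notes and 10.7.3.1 per the file headers. Per the file headers, the processed intensity is background subtracted and detrended within each array, and from the values it is not normalized between arrays. The authors' deposited table for the whole series holds log2 values of 279 probes. Set against the scanner values, these are the log2 processed signal scaled to each array's 75th percentile and centred for each probe on its median over the 6 arrays, with a largest difference of 0.156. How the authors chose these probes is stated only as filters on expression, flags and error. The medians of its columns were 0.32, 0.34 and 0.28 for wild type and -0.29, -0.23 and -0.26 for knockout.

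Each array had 62976 spots, of which 59305 were not controls and covered 55681 probes. All arrays lay on 1 slide and shared 1 scan time, so neither could be tested as a batch. Spots flagged as non-uniform or population outliers, 141 to 283 per array, were set to missing, no spot was saturated, and spots of a probe were averaged. The scanner files give accessions and no gene symbols. Accessions were named without their version through a RefSeq gene table of mouse assembly GRCm38, which named 26413 probes (20018 genes). The other 29268 probes kept the identifier of the file, 16194 of them a chromosome region. The array design refers to an older assembly, so the table was used for names and for the order of neighbouring genes only.

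The main values were log2 of the processed signal minus each array's 75th percentile. At most 51.5% of spots were well above background on an array. Probes were tested when well above background on at least 3 of the 6 arrays, 23085 probes, of which 31 with a missing value on an array were left out. Each gene was represented by its probe with the highest mean level, which left 18405 genes and transcripts, 11759 with a gene name and 6646 without. A gene whose tested probes differed in sign is said so where named. The genotypes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 and Benjamini-Hochberg adjustment over all entries, at an adjusted p of 0.05. No spot was flagged as saturated, but 3 spike-in probes hardly varied over the arrays, between 372999.6 and 581190.8, and genes that reached this range on at least 4 arrays are said to lie at or near the top of the signal range, a rule set after the data were seen. Where a probe was not well above background on any array of a genotype, its fold is a lower bound. The bound sets the mean of the brighter genotype against, per array, the higher of the probe's own level and the lowest level of any spot well above background.

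Gene lists for the functions of these macrophages and for the cells a splenic sort could hold were written before the data were examined, as were the tests, the rule for named genes and most alternatives. Each of 28 lists with at least 5 tested genes was tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance without setting them against other genes, were run beside it and called 0 lists each. A list's shift is its median log2 difference minus that of all tested entries, and its score per array is the mean over its genes after centring each gene on the 6 arrays. Scores were compared by an exact two-sided permutation test, which with 3 against 3 mice cannot go below 0.1. The named genes were Bach2, 10 heme, iron and red pulp macrophage genes, the 12 genes in each direction with the largest changes among those past the threshold, and up to 4 members of each list past the threshold. As no gene passed, the 12 genes were those with the smallest p in each direction, without sex-linked genes, accessions, clones and predicted genes, and 2 members with the smallest p stood for each list, of which 1 is not reported here.

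The fit was tested on simulated data with the same 18405 genes, drawn for 3 against 3 arrays with 200 genes changed in each of 10 draws. It called 0% of genes changed 2-fold, 6.9% of those changed 4-fold and 89.7% of those changed 16-fold, with 47 false calls over all draws. Camera called the shifted list in 10 of 10 draws and the unshifted list in 0. Genes and arrays were drawn independently, whereas the estimated correlation in the real data was 0.35 for the NK list and 0.88 for the cell cycle list. The simulation therefore does not show how often camera calls a list wrongly in these data.

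The alternatives were centring on the array median, quantile normalization, normexp with an offset of 50 followed by the 75th percentile, other filters and probe rules, eBayes with trend and robust, array weights, sex and the shared tag as terms, leaving out both mice with that tag, leaving out each mouse, and other thresholds. Normexp was planned on the mean spot signal and was run on the median spot signal and the median local background, which the files hold. After the data were seen, 4 alternatives were added, namely the 75th percentile over probes detected on all arrays, array column as a block, the erythroid list mean as a covariate, and leaving out the arrays of column 1. Array column was added because the deviations of the 2 mice of a column from their genotype means correlated, at 0.64, 0.17 and 0.29 across genes in columns 1, 2 and 3. Wild-type replicate 2 and knockout replicate 3, which lay in different columns, correlated at 0.31, so across genes only column 1 stood out. The labels link the genotypes only through the shared tag, and the column is a position on the slide.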

Results

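Gene expression was measured in red pulp macrophages, the splenic macrophages that take up aged red blood cells and return their iron to the circulation. The cells were sorted by flow cytometry from C57BL/6 mice of 8 to 9 weeks, 3 wild-type and 3 lacking Bach2, a transcription factor of the BACH family that binds Maf recognition elements. Each mouse gave 1 array with a single Cy3 channel, and all 6 arrays lay on 1 slide. Wild-type replicate 3 was female and the other 5 mice were male. Wild-type RNA lay in array row 1 and knockout RNA in array row 2, so row and genotype cannot be told apart, whereas each of the 3 array columns held 1 mouse of each genotype. Between 37.5% and 51.5% of spots were well above background on an array, and the 75th percentile of the processed signal ranged from 865.2 on wild-type replicate 3 to 3172.1 on knockout replicate 3. Levels are given as log2 signal minus the array's 75th percentile, as mean ± SD over 3 mice, and differences as knockout minus wild type ± SE from limma. The small number of arrays limits the precision of every value.

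Bach2, the deleted gene, was read first. Its brighter probe stood at -0.74 ± 0.70 (SD, n = 3) in wild type and -2.37 ± 1.29 (SD, n = 3) in knockout, a log2 difference of -1.63 ± 0.71 (SE) with a limma adjusted p of 1. The wild-type arrays read -0.90, 0.02 and -1.35, and the knockout arrays read -2.24, -3.72 and -1.15, so knockout replicate 3 overlapped wild type. The probe was well above background on 3 of 3 wild-type and 2 of 3 knockout arrays, and the other Bach2 probe was not well above background on any array. Within array columns 1, 2 and 3 the difference was -1.33, -3.74 and 0.20. The sources used here do not place either probe relative to the deleted part of the gene, so neither probe checks the labels. Ddx3y and Eif2s3y, which lie on the Y chromosome, were well above background on the 5 arrays of male mice and not on that of the female mouse, where Ddx3y read -4.17 and Eif2s3y read -4.36. Neither Xist probe was well above background on any array.

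The study was set up to ask about Bach2 in heme and iron homeostasis, and the main genes of that pathway were abundant in both genotypes. Hmox1, the inducible heme oxygenase that breaks down heme, stood at 7.50 ± 0.82 (SD, n = 3) in wild type and 6.92 ± 0.08 (SD, n = 3) in knockout. Slc40a1, the iron exporter ferroportin, stood at 8.18 ± 0.54 (SD, n = 3) and 7.45 ± 0.19 (SD, n = 3), with no overlap between the genotypes and its signal in the top range on 2 of 6 arrays. The gap was narrow, with wild-type replicate 1 at 7.616 and knockout replicate 1 at 7.591. Spic, the transcription factor that red pulp macrophages require, stood at 6.26 ± 0.49 (SD, n = 3) and 5.85 ± 0.36 (SD, n = 3). The log2 differences were -0.58 ± 0.52 for Hmox1, -0.73 ± 0.46 for Slc40a1 and -0.41 ± 0.47 for Spic (SE), each with a limma adjusted p of 1.

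The other genes of the pathway fixed beforehand also had a limma adjusted p of 1. The ferritin subunits Fth1 and Ftl1 lay at the top of the signal range, where their processed signal varied only 1.41-fold and 1.28-fold over the 6 arrays, so their scaled differences follow the array percentile and are not given. Vcam1, an adhesion molecule of these macrophages, gave -0.62 ± 0.48, the phagosomal metal transporter Slc11a1 gave -0.45 ± 0.45, and the heme transporter Slc48a1 gave -0.33 ± 0.51. Tfrc, the transferrin receptor, gave 0.55 ± 1.11 for its brighter probe, while its other tested probe had the opposite sign. Cd163, the hemoglobin scavenger receptor, was dimmer, at -1.14 ± 1.01 (SD, n = 3) in wild type and -2.43 ± 1.14 (SD, n = 3) in knockout, and only 1 of 3 knockout arrays had it well above background. Among all 1264 tested genes with a mean level of 6 or more, the median log2 difference was -0.34, and within column 3 it was -0.87, against -0.03 and -0.05 within columns 1 and 2. Hmox1 differed by -1.50 in column 3 and by -0.11 and -0.13 in columns 1 and 2.

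**Figure D1:**
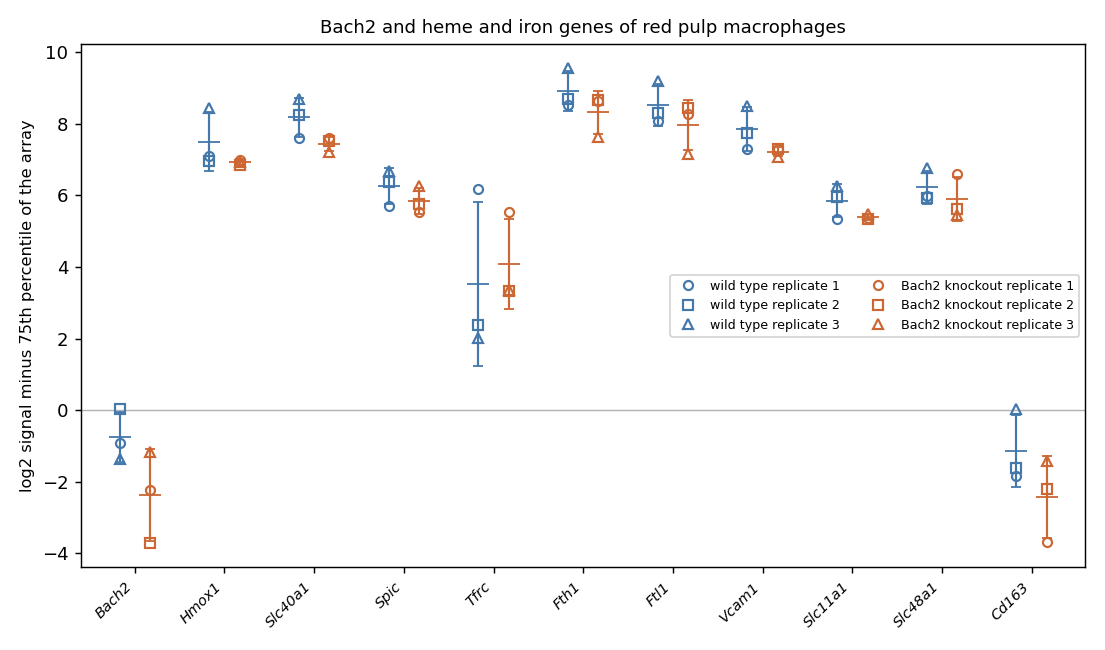
Levels of Bach2 and of 10 heme, iron and red pulp macrophage genes, as log2 signal minus the 75th percentile of the array, in 3 wild-type (blue) and 3 knockout (orange) mice. Symbols mark the replicate, which is also the array column, and bars show mean ± SD; Slc40a1 is the only gene shown whose genotypes do not overlap, and its adjusted p was 1. Fth1 and Ftl1 lie at the top of the signal range.

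As a group, the list for heme breakdown and iron handling had 24 tested genes, of which 17 lay below 0 and 7 above. None passed the test over all genes, none passed when adjusted over the list alone, and the list's median lay -0.22 from the median of all genes (camera adjusted p = 0.183). Leaving out each mouse moved this shift between -0.37 and -0.047, and it was -0.035 with quantile normalization and -0.0051 without both P6-tagged mice. The mean over the list was 0.12 ± 0.21 (SD, n = 3) in wild type and -0.12 ± 0.07 (SD, n = 3) in knockout, with no overlap (exact two-sided permutation p = 0.1, the smallest possible here), and its difference within columns 1, 2 and 3 was -0.15, -0.13 and -0.41. The closest arrays were wild-type replicate 2 at -0.055 and knockout replicate 3 at -0.061. This mean includes Fth1 and Ftl1, at the top of the signal range, whose scaled levels follow the array percentile. That percentile was highest on knockout replicate 3, which lowers both genes there. The lack of overlap therefore depends in part on the scaling and does not establish a lower level of the list. The smallest p values of the list belonged to Cd163, at -1.29 ± 0.73, and Cp, the ferroxidase ceruloplasmin, at 0.90 ± 0.53 (SE). The red pulp macrophage identity list lay lower in knockout, with all 25 tested genes below 0, 22 of them below the median of all genes, and a median shift of -0.26 against all genes (camera adjusted p = 0.001743). No member passed the test, adjusted over the list alone or over all genes. Rxra, a nuclear receptor, read -0.61 ± 0.45 and Trf, transferrin, -0.70 ± 0.51 (SE). Trf reached the top of the signal range on 1 array and its processed signal varied only 1.57-fold, so its scaled difference partly follows the array percentile. The call was lost with an estimated correlation (adjusted p = 0.790), with quantile normalization (shift -0.02) without wild-type replicate 3, the female mouse (shift -0.09), and without knockout replicate 1 (shift -0.25, adjusted p = 0.0621). Its shift within array columns 1, 2 and 3, as the mean over the list, was -0.04, -0.49 and -0.57, beside the difference of the brightest genes in column 3 given above.

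Lists next to this pathway did not pass the test. Targets of Nrf2 and of Maf recognition elements, which encode antioxidant enzymes, had a median shift of -0.13 (camera adjusted p = 0.281), with the exporter Abcc1 at -0.55 ± 0.54 and thioredoxin, Txn1, at -0.45 ± 0.46 (SE). The mean over this list was 0.09 ± 0.07 (SD, n = 3) in wild type and -0.09 ± 0.07 (SD, n = 3) in knockout, without overlap (exact two-sided permutation p = 0.1). Within columns 1, 2 and 3 it differed by -0.06, -0.22 and -0.28. Txn1 reached the top of the signal range on 2 arrays and varied 1.89-fold over the arrays, so its scaled difference partly follows the array percentile. The list of Bach, CNC and small Maf factors, which contains Bach2 itself, also held Maff at -0.86 ± 0.74 (SE). The list gave a camera adjusted p of 0.320 with a direction below that of other genes although its median lay 0.01 above theirs. It was called without both P6-tagged mice (-0.30, adjusted p = 0.0402), a setting in which the deleted gene Bach2 read -2.54. Heme synthesis had a shift of 0.51 (camera adjusted p = 0.118), with Cpox at 0.58 ± 0.83 and Alad at 0.66 ± 1.29 (SE). It was called without wild-type replicate 1 (1.51, adjusted p = 4.22e-06) or knockout replicate 3 (1.10, adjusted p = 0.000577), and its shift was -0.10 without knockout replicate 1. The lysosome list gave a shift of -0.20 (camera adjusted p = 0.0929), with the mannosidase gene Man2b1 at -0.51 ± 0.45 (SE) and the protease gene Ctsb near the top of the signal range, where it varied 1.70-fold over the arrays. It was called in 4 of 21 alternatives, and leaving out each mouse moved its shift between -0.41 and -0.081. The list for lipid uptake, efflux and storage gave -0.07 (camera adjusted p = 0.281), where Pltp, a phospholipid transfer protein, read -1.33 ± 0.80 (SE), and it was called without wild-type replicate 1 (-0.35, adjusted p = 0.0476), with shifts up to 0.064 without other mice. Cholesterol and fatty acid synthesis gave -0.05 (camera adjusted p = 0.741), with Fasn, the fatty acid synthase, at -1.38 ± 0.61 with 1 of 3 knockout arrays well above background, and Mvd at -0.59 ± 0.45 (SE).

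Lists of cytotoxic lymphocytes and T cells were called higher in knockout by camera with its preset correlation, and not with an estimated one. Of 15 tested genes of NK cells and cytotoxicity, all 15 lay above 0, with a median log2 difference of 1.12 (2.18-fold) and a shift of 1.23 against all genes (camera adjusted p = 2.75e-16, with an estimated correlation an adjusted p = 0.269). Gzmb, which encodes granzyme B, stood at 0.20 ± 1.32 (SD, n = 3) in wild type and 3.39 ± 0.90 (SD, n = 3) in knockout, and Gzma, which encodes granzyme A, at 4.78 ± 0.55 (SD, n = 3) and 6.73 ± 1.03 (SD, n = 3). In the T cell list 18 of 20 tested genes lay above 0, with a shift of 0.94 (camera adjusted p = 1.07e-12, with an estimated correlation an adjusted p = 0.269), and the T cell receptor kinases Zap70 and Lck differed by 1.53 ± 0.49 and 1.42 ± 0.50 (SE). The list of type 2 lymphocytes and cytokines, with 4 of 6 tested genes above 0, had a shift of 1.35 (camera adjusted p = 0.0007535, with an estimated correlation an adjusted p = 0.295). In it Gata3, a T helper 2 factor, differed by 2.13 ± 0.77 and Klrg1, a receptor of effector T and NK cells, by 3.09 ± 1.30 (SE), with 1 and 2 of 3 wild-type arrays well above background. The type 2 shift was 0.39 with no filter on dim probes and 0.72 without wild-type replicate 2.

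No member of these 3 lists passed over all genes, with limma adjusted p values of 1 for the genes named, and adjusted over the list alone 1 gene of the NK list passed. The mean over the NK list was -0.58 ± 0.41 (SD, n = 3) in wild type and 0.58 ± 0.67 (SD, n = 3) in knockout, higher in every knockout than in every wild-type array, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 mice allow. The T cell list likewise did not overlap (exact permutation p = 0.1), whereas the type 2 list did (exact permutation p = 0.2). The interferon, heme and iron, and Nrf2 lists did not overlap either, so lack of overlap alone does not set the NK and T cell lists apart. Within array columns 1, 2 and 3 the NK list was higher in knockout by 0.45, 1.49 and 1.56, and the T cell list by 0.72, 0.77 and 0.78. The type 2 list was higher by 0.22, 2.51 and 0.88, most in column 2. Of the lists for other cells that a splenic sort could hold, the B cell list gave a shift of 0.16 (camera adjusted p = 0.363), dendritic cells -0.04 (camera adjusted p = 0.995), inflammatory monocytes 0.01 (camera adjusted p = 0.749) and plasma cells 0.28 (camera adjusted p = 0.0713). The neutrophil (0.95) and erythroid (0.72) lists were also called higher, with the preset correlation only, and are described below. Leaving out each mouse moved the monocyte shift between -0.11 and 0.42. Without wild-type replicate 3 the B cell list was called, with a shift of 0.45 (adjusted p = 0.00130). The plasma cell list was called in 7 of 21 alternatives, and leaving out each mouse moved its shift between -0.0052 and 0.49.

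**Figure D2:**
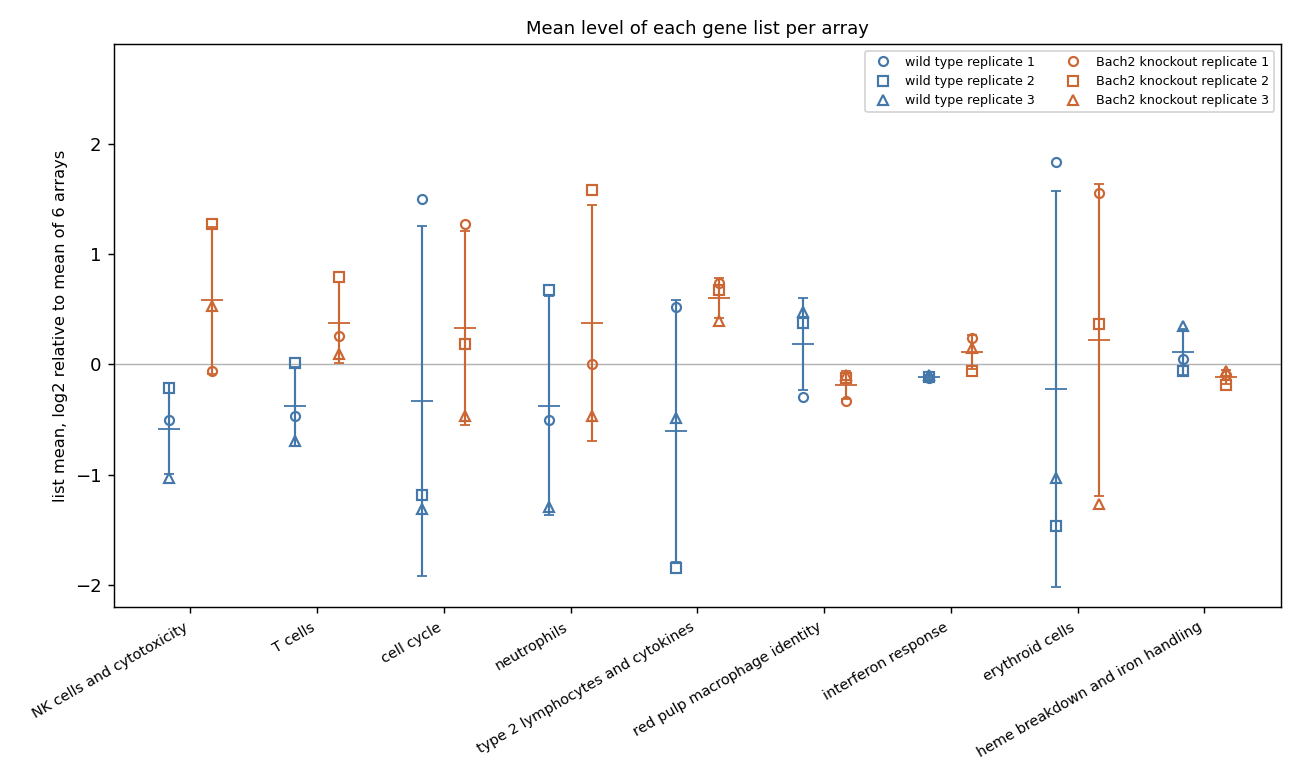
Mean over each gene list per array, in log2 units relative to the mean of the 6 arrays, for the 8 lists called by camera with its preset correlation and for heme breakdown and iron handling. Blue symbols are wild-type and orange symbols knockout mice, and bars show mean ± SD over 3 mice. The NK, T cell and interferon lists are higher in every knockout than in every wild-type array. The heme and iron list is lower by a narrow gap, and its mean includes Fth1 and Ftl1, at the top of the signal range.

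None of the 12 named genes with the smallest p among those higher in knockout passed the threshold. Cxcr6, a chemokine receptor of effector and tissue-resident lymphocytes, stood at -0.62 ± 0.28 (SD, n = 3) in wild type and 1.91 ± 0.59 (SD, n = 3) in knockout, a 5.79-fold difference that both of its tested probes showed. Sh2d1a, the SAP adaptor of T and NK cells, was 4.16-fold higher. Ccl1, a chemokine made by activated T cells, was not well above background on any wild-type array and at least 6.10-fold higher in knockout. The complement gene C4b was 2.96-fold higher and the drug exporter Abcb1b 3.64-fold higher. P2rx5, a receptor for ATP, was at least 4.14-fold higher, Bspry at least 6.67-fold and Aldh1a2, a retinoic acid enzyme, at least 2.47-fold, each against a wild type not well above background. Dusp11 was 7.71-fold higher, with 1 of 3 wild-type arrays well above background, and Gpat3, a glycerol phosphate acyltransferase, 6.03-fold and Wdr95 5.35-fold higher, each with 2 of 3, so these folds rest partly on background. Gzmb completes these 12 genes. For all 12 the genotypes did not overlap, which a choice by smallest p makes likely, and the limma adjusted p was 1.

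Dapl1 had the smallest p of all named genes. It stood at -0.59 ± 1.10 (SD, n = 3) in wild type, was not well above background on any knockout array, and was at least 4.67-fold lower in knockout (limma adjusted p = 0.540). Marco, a scavenger receptor of marginal zone macrophages, stood at 6.19 ± 0.29 (SD, n = 3) in wild type and 4.60 ± 0.49 (SD, n = 3) in knockout, 3.02-fold higher in wild type. The tissue kallikrein genes Klk1b3, Klk1, Klk1b4 and Klk1b24, close relatives in sequence, were 3.01-fold, 2.83-fold, 2.73-fold and 2.75-fold higher in wild type. Cox6a2, a subunit of cytochrome c oxidase, was 3.00-fold and Rnase12 3.22-fold higher in wild type. Alox12, a lipoxygenase, and Get3 were 3.89-fold and 3.05-fold higher in wild type, each with only 1 of 3 knockout arrays well above background, while Grin3b and Rab17 were not well above background in knockout and at least 1.48-fold and at least 1.35-fold higher in wild type. The genotypes did not overlap for any of these 12 genes, which were also chosen by smallest p, and apart from Dapl1 the limma adjusted p was 1.

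**Figure D3:**
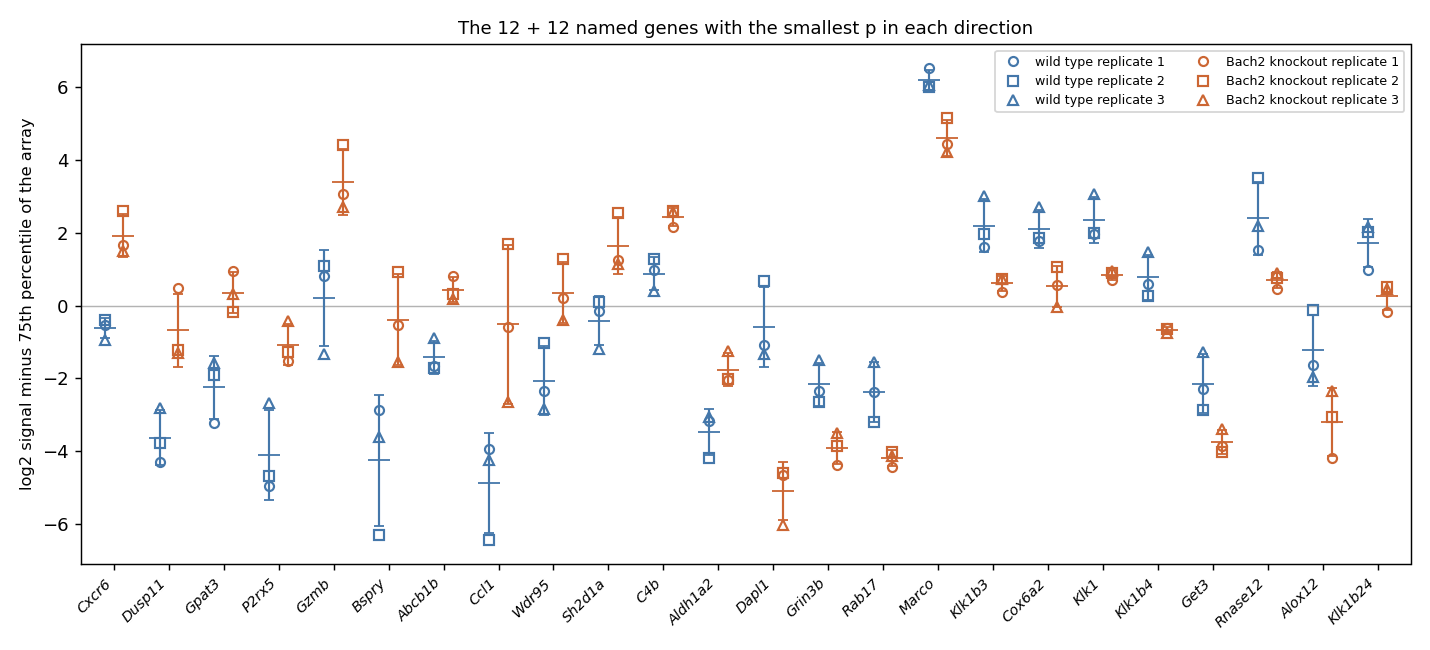
Levels of the 12 named genes with the smallest p among those higher in knockout (left, Cxcr6 to Aldh1a2) and the 12 among those lower (right, Dapl1 to Klk1b24), as log2 signal minus the 75th percentile of the array. Blue symbols are 3 wild-type and orange symbols 3 knockout mice with mean ± SD, and no gene passed an adjusted p of 0.05.

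Across all 18405 genes and transcripts tested, 0 were called higher and 0 lower by limma at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 127 higher and 102 lower, 229 in all, where chance alone gives 920. With array column as a block, 581 had an unadjusted p under 0.05 by limma. Centring each array on its median in place of the 75th percentile gave 192 higher and 46 lower. The genotypes did not overlap for 210 genes on the higher side and 321 on the lower side, 2.89% of those tested, where chance gives 10%. The median of all genes was -0.11, and moved by up to 0.16 with the scaling or the filter, so that list shifts are given against it.

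Of the other lists called, those of neutrophils, dividing cells and erythroid cells varied widely between mice of a genotype. Neutrophil genes gave a shift of 0.95 (camera adjusted p = 3.90e-06), with lactoferrin, Ltf, at 1.64 ± 0.69 and Ngp, a granule protein, at 1.35 ± 0.57 (SE). Of 26 cell cycle genes 24 lay above 0 and all 26 above the median of all genes, with a shift of 0.85 (camera adjusted p = 3.90e-06), with Cdc20 at 1.19 ± 0.88 and the kinesin Cenpe at 1.17 ± 1.07 (SE). Erythroid genes gave a shift of 0.72 (camera adjusted p = 0.0371), with Epb42, a red cell membrane protein, at 1.12 ± 1.26 (SE), while Hba-a2, an alpha globin gene, lay at the top of the signal range with a 1.16-fold spread over the arrays. The interferon response list gave a shift of 0.20 (camera adjusted p = 0.0311), with the guanylate binding protein Gbp2 at 1.07 ± 0.48 (SE). No member of these 4 lists passed over all genes or adjusted over the list alone, and with an estimated correlation the lists gave an adjusted p = 0.790 for neutrophils and for the cell cycle, an adjusted p = 0.823 for erythroid cells and an adjusted p = 0.295 for interferon.

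The mean over the erythroid list read 1.84, -1.47 and -1.03 on the wild-type arrays and 1.55, 0.36 and -1.26 on the knockout arrays, and the cell cycle list read 1.50, -1.18 and -1.31 against 1.27, 0.19 and -0.47. The erythroid list thus differed by -0.28, 1.83 and -0.23 within columns 1, 2 and 3, and the cell cycle list by -0.23, 1.37 and 0.84. The erythroid shift changed sign without wild-type replicate 2 (-0.09) or knockout replicate 1 (-0.03), and the call was lost without wild-type replicate 3 (0.16) or knockout replicate 2 (0.65); the cell cycle call was lost without wild-type replicate 2 (0.27), wild-type replicate 3 (0.21) or knockout replicate 1 (0.28). The neutrophil call was lost without knockout replicate 2 (0.12), and the interferon call without wild-type replicate 1 (0.27) or 2 (0.18) or knockout replicate 1 (0.19) or 3 (0.23).

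The remaining lists did not pass the test, and no gene in them passed over all genes or adjusted over the list alone. Platelet and megakaryocyte genes gave a shift of -0.50 (camera adjusted p = 0.0727), with Pf4, platelet factor 4, at -1.51 ± 0.99 and Treml1 at -1.77 ± 1.07 (SE). The platelet list was called in 11 of 21 alternatives, among them median centring (adjusted p = 0.0296), normexp (adjusted p = 0.0172) and no filter on dim probes (adjusted p = 0.00180). Leaving out each mouse moved its shift between -0.85 and -0.087. In the B cell list, Cr2, a complement receptor, read -1.25 ± 0.52 and the coactivator Pou2af1 0.68 ± 0.55 (SE). Plasma cell genes included Sdc1 at 0.65 ± 0.56 and Tnfrsf17 at 0.84 ± 0.85 (SE). Among monocyte genes F13a1 read -1.64 ± 0.92 and Itgam -0.92 ± 0.68 (SE), the latter with a further probe of opposite sign, and among dendritic cell genes Siglech read -0.47 ± 0.46 and Xcr1 0.72 ± 0.73 (SE). The processed signal of Siglech varied only 1.81-fold over the arrays, so its scaled difference partly follows the array percentile. The list of eosinophils, basophils and mast cells gave a shift of 0.18 (camera adjusted p = 0.281), with Cpa3, a mast cell protease, at 2.21 ± 1.19 (well above background on 1 of 3 wild-type and 2 of 3 knockout arrays) and Il5ra at 1.002 ± 0.78 (SE). It was called without wild-type replicate 2 (0.14, adjusted p = 0.0427). Endothelial and stromal cells gave -0.00231 (camera adjusted p = 0.810), with Kdr at -0.42 ± 0.57 and Ccl19 at -0.35 ± 0.60 (SE), the latter with a further probe of opposite sign.

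Programmes of macrophage activation did not pass in the main setting, and 4 of these lists were called on leaving out a mouse: MHC class II without wild-type replicate 1 (-0.31), alternative activation without knockout replicate 1 (0.31), inflammatory activation without wild-type replicate 3 (0.16), and immediate early genes without wild-type replicate 3 (0.46) or knockout replicate 1 (0.45). Presentation by MHC class II gave a shift of -0.13 (camera adjusted p = 0.259), with H2-Ab1 and the protease Ctss near the top of the signal range, where they varied 1.35-fold and 1.41-fold over the arrays. Alternative activation gave 0.15 (camera adjusted p = 0.157), with the chemokine Ccl17 at 1.17 ± 0.49 and Pdcd1lg2 at 0.99 ± 0.78 (SE). Inflammatory activation had a median 0.02 below that of all genes but a camera direction above it (camera adjusted p = 0.363), with the chemokines Cxcl9 at 1.07 ± 0.54 and Ccl3 at 1.99 ± 1.18 (SE). Clearance of apoptotic cells and pathogens, which holds Marco and C4b, gave -0.15 (camera adjusted p = 0.601). Immediate early and stress genes gave 0.19 (camera adjusted p = 0.410), with Junb at -1.46 ± 0.53 and Atf3 at 1.23 ± 0.64 (SE), and glycolysis and hypoxia gave -0.00698 with a camera direction above that of other genes (camera adjusted p = 0.899), with Pfkp at 0.45 ± 0.42 and Adm at -0.61 ± 0.59 (SE). Of the list members named, Maff, Xcr1, Ccl17, Ccl3, Treml1 and Adm were also well above background on only 1 or 2 of 3 arrays of a genotype.

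None of the 100 tested genes nearest to Bach2 on chromosome 4, 50 on each side, passed an adjusted p under 0.05, and 0 had an unadjusted p under 0.05 by limma, against 128 of 11658 other genes with a known position (Fisher's exact test, two-sided, p = 0.630). At the rate of the other genes 1.1 would be expected, so this test could hardly show a difference. The authors' deposited table for the whole series held 279 probes, of which 68 were higher and 211 lower in knockout on average. Every probe in it separated the 3 knockout from the 3 wild-type arrays without overlap, so the table was chosen on these samples and its directions are not independent evidence. Of its probes other than 1 spike-in control, 100% had the same direction here. In the probe-wise limma fit 145 of them passed the filter on dim probes, of which 0 had an adjusted p under 0.05 and 71 an unadjusted p under 0.05.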

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

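The tests of the splits of the arrays and of naive against effector genes were planned before their results were seen, and the other tests in this part were chosen after. Of 10 Agilent spike-in probes, which no comparison used, 6 varied more between arrays than the 75th percentile of all probes, which spanned 865.2 to 3172.1, and 4 varied less. Among those above background on every array, the one that varied most spanned a 23.46-fold range. No group of 3 mice could be tested for a sample far from the others.

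In their spike-in signals, the arrays of a slide column resembled each other across genotypes. Across genes only column 1 stood out, as described above. A bright spike-in probe, E1A_r60_a135, read 57869.5 and 32351.2 in column 1, 177667.6 and 103675.9 in column 2, and 8223.3 and 13846.0 in column 3, wild type first. The mean absolute log2 difference of the spike-ins between the 2 arrays of a column was 0.548, against 0.822 for the next of the 6 ways to match wild-type to knockout arrays, and 6 matchings are too few for a share under 0.05. Preparation of each column's arrays together may account for this but cannot be told apart from chance with so few matchings. Differing erythroid RNA in column 1 stays open as well: 85% of the 20 erythroid genes were higher on both its arrays than on the other 4, against 15% of all other genes, but so were 88.46% of cell cycle and 83.33% of heme synthesis genes, and the erythroid scores had been seen before.

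With 3 against 3 mice there are 10 splits of the arrays, too few for a share under 0.05. All 10 gave at least the 0 genes of the real split past an adjusted p of 0.05, and the highest other split gave 459. At an unadjusted p under 0.05, 9 of 10 gave at least the real 229 genes and the highest other gave 3809. For genes whose groups did not overlap, 9 of 10 gave at least the real 531 and the highest other gave 5016. For lists called by camera, 6 of 10 gave at least the real 8 and the highest other gave 12. Most splits put both arrays of a column on 1 side, unlike the real one. The other splits with 1 array of each column per side gave 301, 340 and 126 genes at an unadjusted p under 0.05, and 1, 2 and 12 lists. The split that called 459 genes set wild-type replicate 1 with knockout replicates 1 and 2 against the rest, which points to a structure of the samples other than genotype. These 3 arrays had the higher erythroid scores, 1.84, 1.55 and 0.36, against -1.47, -1.03 and -1.26 on the rest. Knockout replicate 2 lay in column 2, so a column block does not remove this structure as a whole. With array column as a block, 0 genes passed an adjusted p of 0.05 and 581 an unadjusted p under 0.05.

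The NK and T cell lists were higher in every knockout than in every wild-type array. A lower share of macrophages, which would raise every other cell type alike, stays open. The NK and T cell lists were picked for this test after their shifts were seen, so a lead over less shifted lists was partly built in. The score of 35 NK and T cell genes was higher in knockout by 0.97 ± 0.43 (SE), 2.24 SE, than that of 53 B cell, dendritic cell and monocyte genes. This difference was above 0 in each column (0.402, 1.477 and 1.025), although wild-type replicate 1 (0.144) lay above knockout replicate 3 (-0.003). The bar of 2 SE was settled after the values were seen, where a stricter bar of no overlap was not met. Against the mean of 9 lists of other cells, a comparator added after that result, the NK and T cell score was higher by 0.85 ± 0.10 (SE) without overlap. The neutrophil list, with a shift of 0.95, moved with the NK and T cell lists. The female wild-type mouse as the whole source is only weakly argued against. Among the 5 male mice the NK and T score was still higher by 0.75 ± 0.33 (SE), 2.24 SE. Their lack of overlap follows from that of all arrays and adds nothing, and here too the bar was set after the values were seen. A shift of lymphocyte RNA from naive to effector genes stays open. The 15 effector genes had larger differences than 10 naive genes (one-sided permutation p over genes = 0.0231), which treats genes as independent. Of these, 9 effector and 3 naive genes were in the NK or T cell lists, which were called higher. Over arrays the effector minus naive score differed by 0.62 ± 0.45 (SE). In that score wild-type replicate 1 (0.29) lay above knockout replicates 1 (0.02) and 3 (0.05). More NK and T cells in the sorted fraction, whose gate is not given in the sources used here, and a change within the macrophages are untested, as is array row.

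The red pulp macrophage list was lower in knockout, with a mean log2 difference of -0.366. A difference shared by all probes of the same brightness may account for much of it, as random lists matched on mean level had a mean of -0.235. A share of 0.0184 of 10000 such lists was as low, which treats genes as independent, while quantile normalization, which removes differences by brightness, ended the call with a shift of -0.02 (adjusted p = 0.673). The tables point both ways, so this explanation cannot be told apart from a lower level of these genes in the knockout fraction.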

How the results depend on the processing

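The percentile over detected probes, the column block, the erythroid covariate and leaving out column 1 were chosen after the data were seen. The count of genes past an adjusted p of 0.05 was 0 in each direction under every alternative with that threshold or 0.1, with 110 to 808 genes at an unadjusted p under 0.05 (127 higher and 102 lower in the main setting, and 808 without wild-type replicate 1). The lowest adjusted p was 0.250 in the main setting and 0.111 over the alternatives. Camera called 8 lists, 7 to 12 under alternatives that kept its preset correlation, and 0 with an estimated correlation or by fry. Bach2 kept its direction under every alternative computed, between -2.54 without both P6-tagged mice and -0.95 without knockout replicate 2, with an adjusted p of 0.998 to 1. The authors' table had 100% of probes in the same direction under normexp and quantile normalization. For the neighbours of Bach2 the count was 0 with 25 genes on each side, with up to 100 on each side (154 in all) and at an unadjusted p under 0.05.

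The NK, T cell and type 2 lists stayed called under every alternative that kept the preset correlation, except that the type 2 list had too few genes for a test with probes well above background on all 6 arrays; its shift ranged from 0.39 with no filter on dim probes to 1.90 without wild-type replicate 1. With an estimated correlation or fry, which leave the shifts as they are, the calls ended for NK cells (1.23), T cells (0.94), type 2 lymphocytes (1.35), neutrophils (0.95), cell cycle (0.85), erythroid cells (0.72), interferon response (0.20) and red pulp macrophages (-0.26). The red pulp macrophage call also ended with quantile normalization (-0.024), with sex as a covariate (-0.092), which equals leaving out the female mouse, without both P6-tagged mice (-0.13) and without knockout replicate 1 (-0.25, adjusted p = 0.0621). The cell cycle call ended with sex as a covariate (0.21). The interferon call ended with no filter on dim probes (0.039), with array weights (0.27), without both P6-tagged mice (0.25) and without column 1 (0.051). The erythroid call ended with no filter on dim probes (0.55), sex as a covariate (0.16), the percentile over detected probes (0.72) and the erythroid covariate (0.20), which removes it by construction. Leaving out each mouse gave shifts of -0.49 to -0.092 for red pulp macrophages, -0.087 to 2.01 for erythroid cells, 0.12 to 1.47 for neutrophils, 0.18 to 0.28 for interferon and 0.21 to 1.93 for the cell cycle. Array column as a block ended none of the 8 calls and added heme synthesis (adjusted p = 0.0303) and platelets and megakaryocytes (adjusted p = 0.0104). Other lists not called in the main setting were called under some alternatives, platelets in 11 of 21 and plasma cells in 7 of 21, and without single mice B cells (0.45, without wild-type replicate 3) and heme synthesis (1.51, without wild-type replicate 1). The heme breakdown and iron list was never called, with shifts of -0.37 to -0.0051. Apart from these constructions, the cause was not tested. The labels pair the genotypes only by 1 shared tag, and the column block pairs them by slide position.

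Of the 84 other named genes, 72 kept their direction under every alternative and none passed an adjusted p of 0.05 in the 1596 alternatives computed. Tfrc turned to -0.12 with the mean of its probes and -0.21 with sex as a covariate, and Alad to -0.00044 with sex as a covariate. Without both P6-tagged mice Fth1 (0.051), Ftl1 (0.16), Slc48a1 (0.16), Hba-a2 (0.25), H2-Ab1 (0.13), Ctss (0.0088), Ctsb (0.0039), Kdr (0.085) and Ccl19 (0.075) turned upward. With quantile normalization Hba-a2 (0.031) and Ctss (0.027) did. Of these, Fth1, Ftl1, Hba-a2, H2-Ab1, Ctss and Ctsb lay at or near the top of the signal range, where the scaling sets the sign. Leaving out each mouse moved Tfrc between -0.21 and 1.87, Alad between -0.22 and 2.08, Tnfrsf17 between -0.13 and 1.62 and Ccl19 between -0.78 and 0.23. The other genes that changed sign, Tfrc, Alad, Slc48a1, Kdr, Tnfrsf17 and Ccl19, were well above background on every array. Across all probes, at most 51.5% of spots were well above background on any array.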

Other observations

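Several entries with the smallest p carry no gene name here. The smallest belonged to a probe for a region of chromosome 14 at positions 99728359 to 99728958 of the assembly named in the file headers (mm9), which stood at -4.05 ± 0.57 (SD, n = 3) in wild type and -0.0023 ± 0.22 (SD, n = 3) in knockout, a log2 difference of 4.05 ± 0.47 (SE, limma adjusted p = 0.250). It was well above background on 1 of 3 wild-type and 3 of 3 knockout arrays, and whether the region lies in a gene was not analysed here. The transcript ENSMUST00000122399 was higher in knockout by 4.35 ± 0.53 (SE, limma adjusted p = 0.250) and ENSMUST00000103422 lower by a log2 difference of -4.71 ± 0.64 (SE, limma adjusted p = 0.365). The former was well above background on 2 of 3 wild-type arrays and the latter on 2 of 3 knockout arrays, so both differences rest partly on background.

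Among effector genes outside the named set, chosen after their values were seen, Ifng, which encodes interferon gamma, differed by 1.81 ± 0.57 and Il18r1, a receptor chain for interleukin 18, by 1.83 ± 0.59 (SE, limma adjusted p of 1 for each). Of the naive markers, Tcf7 differed by 0.05 ± 0.53 (SE, limma adjusted p of 1). The authors' deposited table names Gzmk, a further granzyme gene picked here after its values were seen, at -1.68, -2.30 and -2.91 on the wild-type arrays and 1.69, 2.77 and 1.68 on the knockout arrays, as log2 values centred over the 6 arrays. The same table lists Eomes, a transcription factor of cytotoxic lymphocytes, at -0.14, -0.28 and -0.41 in wild type and 0.14, 1.34 and 0.97 in knockout. Its probes were kept for separating these arrays, so these values are not independent evidence of the direction.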
